A study of Bos taurus with 28 samples.

How the data were processed

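Bovine conceptuses were profiled by mRNA sequencing on days 7, 10, 13, 16 and 19 of development in 28 libraries. Per the labels' protocols, embryos came from synchronised beef heifers inseminated from a single bull; heifers of days 7 and 10 were superovulated and their embryos pooled in groups of 5, and later conceptuses were processed singly. The protocols name 5 replicates per stage, while the labels hold 6 libraries for day 7 and 7 for day 10. The sample characteristics of day 13 instead state a pool and superovulation, so the 2 kinds of label disagree there. Per the labels' protocols, polyadenylated RNA was taken directly from embryos of days 7, 10 and 13, whereas total RNA was prepared first for days 16 and 19. The RNA preparation and the step from day 13 to day 16 therefore cannot be told apart, nor, by these protocols, can pooling and superovulation and the step from day 10 to day 13.

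The authors deposited one RPKM value (reads per kilobase of transcript, scaled to the library total) for each of 28054 Ensembl bovine transcript identifiers in each library. CASAVA is named, per the submitters' processing notes, without a version or role. The aligner settings, genome build and annotation release are not given in the sources used here. In each library, every value above 0 was a whole number of reads divided by a transcript length and a library total, so reads, lengths and totals were recovered from the deposited RPKM values. After recovery, 100.0% of the values above 0 came out whole within 1e-06 of a read, and the recovered reads made up at least 99.978% of each library total. Totals ran from 473552 to 10871501 reads. Intervals and limits given for reads cover counting error only, because molecules copied by PCR are not independent.

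The files do not pair transcript identifiers with gene names. None of the 28054 identifiers matched the RefSeq gene table supplied (37063 genes, assembly ARS-UCD2.0), in which 0 entries carry an Ensembl bovine identifier. The 30 gene lists and the panel of named genes fixed in advance were therefore not analysed here. Transcripts are named by identifier: for each comparison, up to 2 that rose and 2 that fell, taken as the largest log2 changes among called transcripts whose replicates on the 2 days did not overlap and whose mean was at least 5 RPKM on the higher day. That form of the rule, without gene names, was set after the values were read; where 1 transcript was called in all, it is named.

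Group membership follows the sample labels. In 12 libraries the file carries the title of another sample, and in 3 of them that title belongs to another day: day 16 replicate 5 (file titled for day 19), day 19 replicate 5 (day 7) and day 7 replicate 6 (day 16). These 3 libraries were left out of the comparisons. The file name of day 7 replicate 6 also carries a day mark, day 7, which matches its label. The reads of each pair of libraries were compared by chi-square over transcripts with at least 10 reads in the pair, leaving out the most abundant transcript. Day 16 replicates 2 and 3 had a mean chi-square of 1.19 per transcript, where sampling noise alone gives 1, and 7.27% of 15908 transcripts passed the 5% point. The 5 other pairs of day 16 had means of 5.38 to 18.0. They differed by little more than sampling noise and were counted as 1 sample, with the mean of their RPKM values and the sum of their reads. The plan had counted them as 2. The change, and the limit of 1.5 on the mean chi-square behind it, were made after the counts with 2 samples had been seen: 274 transcripts for day 13 against day 10, 2153 for day 16 against day 13, 78 for day 19 against day 16 and 2789 over the 5 days. With 1 sample these are 229, 1399, 45 and 2131, so the change lowered each. Day 10 replicates 4 and 5 stayed 2 samples, with a mean chi-square of 4.49 at 5106242 and 5202316 reads. It was the lowest among the other pairs of 1 day, and this measure grows with depth. At 300000 reads their Pearson correlation was 0.949, against 0.944 for the merged day 16 pair and 0.947 for day 13 replicates 3 and 4. Whether they share material cannot be told from these values. If they do, n = 7 overstates the day 10 replicates. In all, 24 replicates remained: 5 on day 7, 7 on day 10, 5 on day 13, 3 on day 16 and 4 on day 19. The labels name separate conceptuses or pools but not the heifer of each, so p-values measure the spread between these samples.

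Changes were tested with limma (version 3.58.1, R 4.3.3; lmFit, then eBayes with trend and robust) on log2(RPKM + 1), with the 5 days in 1 model and a contrast for each pair of consecutive days. Transcripts with at least 1 RPKM in at least 4 replicates were tested, 19186 in all. Day 16 has 3 replicates, so transcripts that reach this level on day 16 alone were not tested. Each alternative applied the filter anew to the replicates and values it used, unless it changed the filter itself. A transcript was called at a Benjamini-Hochberg adjusted p under 0.05 and a log2 change of at least 1. A change on this scale understates that of weakly expressed transcripts. The moderated F test of the same model, with a range of day means of at least 1, gave the transcripts that varied over the 5 days. The comparisons, this test, the omission of the 3 libraries and the first set of alternatives were chosen before the data were examined. The library measures and their tests were chosen afterwards. Library measures were compared by exact two-sided permutation tests, adjusted over a family of 8 (scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, Python 3.11.15; plots with matplotlib 3.10.9). For measures at equal depth, reads without the most abundant transcript were thinned to 300000 per library.

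The test was tried on simulated reads with the real totals, in which 100 transcripts changed by 1.5 and 100 by 3 on the log2 scale. Only transcripts with a mean of at least 5 RPKM were changed, and the simulated spread of each was capped at a log2 SD of 1, so recovery in the real data is lower for transcripts that vary more or are weaker. Of those changed by 3, 95% were recovered for day 10 against day 7, 95% for day 13 against day 10, 80% for day 16 against day 13 and 67% for day 19 against day 16. Of those changed by 1.5, 38%, 33%, 20% and 14% were recovered in the same order. The day 10 simulation ran on 18740 transcripts and called 16 that had not been changed.

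Alternatives varied the pseudocount (0.1 and 0.5), the filter on low values, the scaling between libraries, the samples in the model, the variance model and each replicate in turn. After the values were seen, limma voom on the recovered reads, equal depth, totals without the most abundant transcript, total reads as a covariate, day 16 replicates 2 and 3 as separate samples, and the omission of libraries that stood apart were added. The planned count tests on recovered reads were not run, since the deposited unit is RPKM; voom stands in their place.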

Results

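The study followed the bovine conceptus, the embryo with the membranes it forms, from the blastocyst to the start of implantation, and asked how its transcripts change with stage. Day 7 stands for the blastocyst and day 10 for the sphere that has left the zona. The ovoid conceptus that begins to elongate was taken on day 13. Day 16 is the filament at maternal recognition of pregnancy, when the conceptus signals its presence to the mother, and day 19 the filament that begins to attach. By label there were 6 libraries on day 7, 7 on day 10 and 5 on each later day; 24 replicates entered the comparisons. Total reads per replicate, in units of 1e6 (M), averaged 2.29 ± 2.30 M on day 7 (SD, n = 5), 2.30 ± 2.07 M on day 10 (n = 7), 2.61 ± 1.19 M on day 16 (n = 3) and 9.26 ± 2.63 M on day 19 (n = 4). On day 13 they ran from 1.23 to 6.50 M (n = 5). The shallowest library, day 7 replicate 5, held 473552 reads, so a transcript without a read there could still lie at up to 6.34 CPM; in the deepest, day 19 replicate 3, that limit was 0.276.

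A single short transcript, ENSBTAT00000042502 (92 nucleotides, singled out after its values were seen), had the highest RPKM in 22 of the 28 libraries. It took 38.4% of the reads of day 10 replicate 7 (95% Wilson interval 38.3 to 38.5) and 34.3% of day 7 replicate 5 (34.2 to 34.5), against at most 5.11% in any other library. Among the remaining reads, the 10 most abundant transcripts held 5.81 ± 0.94% on day 13 (SD, n = 5) and 9.20 ± 1.94% on day 16 (n = 3), and all 3 day 16 values lay above all 5 of day 13 (exact permutation test, two-sided p = 0.0357, the smallest these group sizes allow; adjusted p = 0.143 over 8 tests). At 300000 reads, 13391 ± 524 transcripts had a read on day 13 and 15531 ± 956 on day 16, again without overlap (exact permutation test, p = 0.0357; adjusted p = 0.143). On day 19 the number was 12946 ± 183 (n = 4), below all 3 day 16 values (exact permutation test, p = 0.0571, the smallest possible with 3 against 4; adjusted p = 0.152). None of the 8 tests passed after adjustment, and the other 5 had adjusted p of 0.606 or more.

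**Figure D1:**
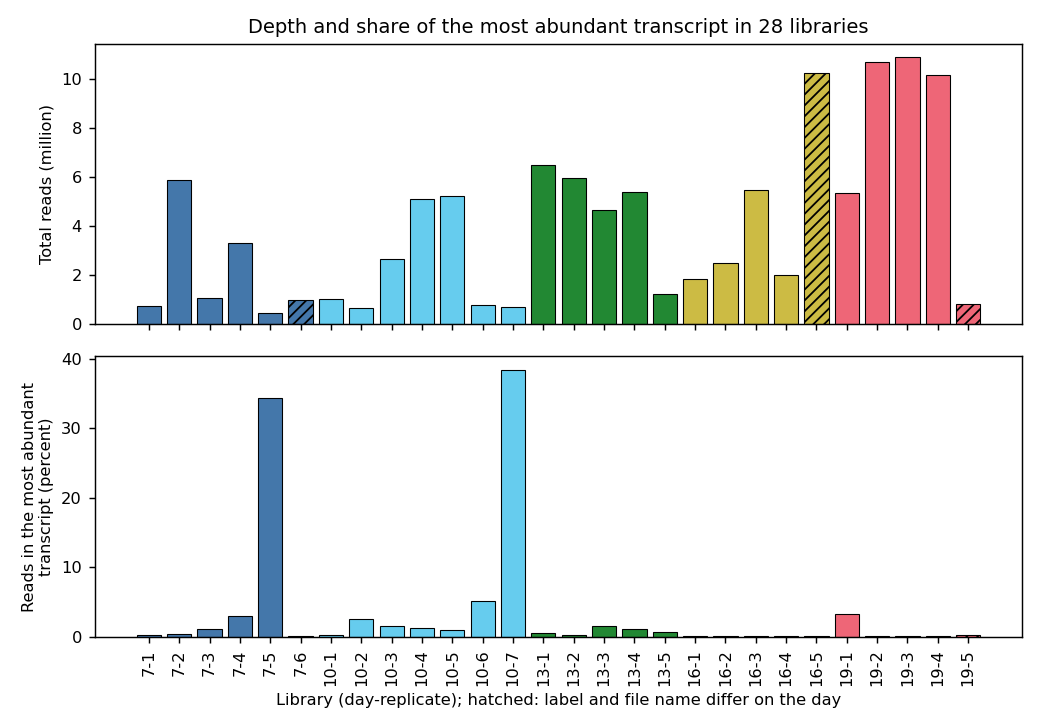
Bars give total reads (M) and the percent of reads in the most abundant transcript for each of the 28 libraries, coloured by labelled day. Hatching marks files that carry the title of a sample of another day. Day 10 replicate 7 and day 7 replicate 5 stand out at 38.4% and 34.3%.

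Pooled over all days, replicates of a day resembled each other little more than replicates of different days. The mean Spearman correlation across transcripts was 0.804 ± 0.117 (SD) over 50 pairs of a day and 0.778 over 226 pairs of different days. At full depth day 19 was the most uniform, with a mean of 0.960 over 6 pairs, and day 10 the least, with 0.739 over 21 pairs. Total reads differed too, with means of 9.26 M on day 19 and 2.30 M on day 10. At equal depth, Pearson correlations were 0.917 to 0.945 between day 19 replicates and 0.926 to 0.947 among day 13 replicates 1 to 4. The first place of day 19 can therefore come from its depth and from day 13 replicate 5. Day 10 replicates correlated with those of day 19 at 0.796 on average at full depth, above their mean with each other. The pooled picture did not hold on every day. Day 13 replicates had a mean of 0.872 with each other and 0.756 to 0.836 with the other days. For day 19 the mean of 0.960 stood against 0.776 to 0.875. Correlations across transcripts describe the libraries and are not independent observations.

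**Figure D2:**
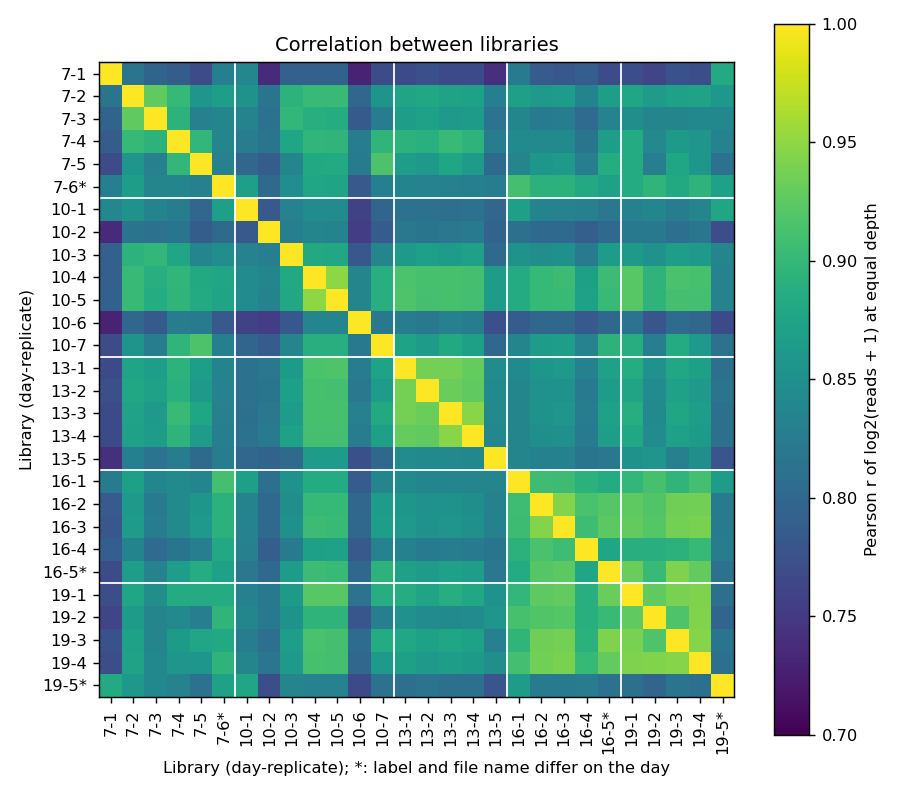
Colour gives the Pearson correlation of log2(reads + 1) between the 28 libraries at 300000 reads each, ordered by labelled day and replicate on both axes, with white lines between days. Day 19 replicate 5, whose file carries a day 7 title, lies apart from the other day 19 libraries at 0.798 to 0.815.

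The first comparison asked what changes between the blastocyst and the hatched sphere. One transcript rose and 0 fell among 19186 tested. ENSBTAT00000011088 (1063 nucleotides) had no read in any of 5 day 7 replicates, over 11.5 M reads. On day 10 it stood at 66.6 ± 61.0 RPKM (SD, n = 7), with a log2 change of 5.05 ± 0.75 (SE, limma, adjusted p = 0.00645). That mean was at least 270.4-fold above the 0.246 RPKM that 3 reads over the whole of day 7 would give. A read was present in 7 of 7 day 10 replicates, but replicate 3 lay near that floor at 0.355 RPKM. Replicates 4 and 5 were the highest, at 142 and 149 RPKM. The transcript stood at 23.3 ± 13.3 RPKM on day 13 (n = 5) and at 0.149 ± 0.258 on day 16 (n = 3). In all, 1828 transcripts had a limma p under 0.05 before adjustment, and voom on the recovered reads called 111, of which 12 were higher and ENSBTAT00000011088 was not among them (adjusted p = 0.0635). Single libraries governed the count: it was 92 without day 7 replicate 5, 56 without day 10 replicate 7, 28 without day 10 replicate 3, 19 without day 10 replicate 1, 3 without day 7 replicate 1, and 2 without either day 7 replicate 4 or day 10 replicate 6. Without the pair of libraries rich in the 92-nucleotide transcript, 108 were called, 46 higher and 62 lower, and the model of these 2 days alone called 0. That pair, 1 library of each day, had a Pearson correlation of 0.917 at equal depth, above that of either with any other library.

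The second comparison covered the onset of elongation, from day 10 to day 13. In all, 229 transcripts changed (1.19% of those tested), with 127 higher and 102 lower on day 13. With the pseudocount of 1, 14 transcripts fell by at least 4 on the log2 scale and 0 rose by as much, but a smaller pseudocount enlarges rises from low levels: that of ENSBTAT00000030336 was 4.04 with 0.5 (adjusted p = 0.0202) and 5.37 with 0.1 (adjusted p = 0.0388). ENSBTAT00000048580 fell from 917 ± 584 RPKM (SD, n = 7) to 90.3 ± 191 (n = 5), with a log2 change of -5.84 ± 0.77 (SE; adjusted p = 2.8e-04), and ENSBTAT00000005399 fell from 2183 ± 1417 to 84.2 ± 112 RPKM (log2 change -5.05 ± 0.70, adjusted p = 3.1e-04). Among the rises, ENSBTAT00000010124 went from 8.06 ± 7.42 to 64.1 ± 38.1 RPKM (log2 change 3.36 ± 0.71, adjusted p = 0.0146) and ENSBTAT00000030336 from 5.89 ± 7.35 to 39.4 ± 27.1 RPKM (log2 change 3.47 ± 0.72, adjusted p = 0.0133). Both were back at 4.97 ± 0.58 and 5.72 ± 1.63 RPKM on day 16 (n = 3). Of the falling transcripts, ENSBTAT00000048580 stood at 1072 ± 109 RPKM on day 16, above its day 10 mean. ENSBTAT00000005399 rose again to 875 ± 43.8 RPKM, below its day 10 mean of 2183.

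Day 13 replicate 5 was the highest of its day in both named falls. ENSBTAT00000048580 was at 431 RPKM there, 8.76 on the log2 scale, against 1.99 to 2.96 in the other 4. ENSBTAT00000005399 was at 282 RPKM there, against 17.1 to 57.0 in the other 4. Without day 13 replicate 5, 350 transcripts were called, 164 higher and 186 lower. The count was 95 without day 13 replicate 1, 92 without replicate 2 and 90 without replicate 3. By the protocols, pooling and superovulation changed with this step too, so their part cannot be told from that of stage. The balance of rises and falls was not stable: the model of these 2 days alone called 35, 13 higher and 22 lower, a pseudocount of 0.1 gave 74 higher and 128 lower, and voom 197 higher and 422 lower. Depth differed between these days, and at equal depth 109 transcripts were called, 30 higher and 79 lower, while total reads as a covariate left 83. The rise of ENSBTAT00000010124 kept its call at equal depth (log2 change 3.38, adjusted p = 0.0313) and lost it with the covariate (2.54, adjusted p = 0.109) and with a pseudocount of 0.1 (4.07, adjusted p = 0.115). That of ENSBTAT00000030336 lost its call at equal depth (3.11, adjusted p = 0.0904), with the covariate (3.00, adjusted p = 0.0872), in the 2-day model (3.47, adjusted p = 0.0834) and without the 3 libraries that stood apart (2.87, adjusted p = 0.0521).

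The third comparison spanned days 13 and 16, when the conceptus becomes a filament, and held the most changes of the 4: 1399 transcripts (7.29%), 970 higher and 429 lower on day 16. Of these, 130 rose and 19 fell by at least 4 on the log2 scale. ENSBTAT00000053388 reached 13797 ± 4319 RPKM on day 16 (SD, n = 3) from 835 ± 1857 on day 13 (n = 5; log2 change 9.46 ± 1.60 SE, adjusted p = 8.9e-04), and ENSBTAT00000018521 reached 17356 ± 5713 from 1134 ± 2523 (log2 change 9.39 ± 1.59, adjusted p = 8.9e-04). Day 13 replicate 5 carried both day 13 means, at 4158 and 5648 RPKM against at most 8.69 and 9.53 in the other 4, and without it the changes were 11.41 and 11.35. ENSBTAT00000017619 fell from 66.02 ± 14.29 to 1.12 ± 1.71 RPKM (log2 change -5.24 ± 0.77, adjusted p = 2.5e-04), and ENSBTAT00000057026 from 78.0 ± 70.4 to 0.465 ± 0.805 RPKM (log2 change -5.42 ± 1.31, adjusted p = 0.0113). The call of ENSBTAT00000057026 ended at equal depth (log2 change -4.53, adjusted p = 0.141), without day 16 replicates 2 and 3 (1 sample; -5.21, adjusted p = 0.0542) and without day 16 replicate 4 (-5.21, adjusted p = 0.0709), although the change stayed large. A further set of 181 transcripts had a read in every day 16 replicate, at a mean of at least 5 RPKM, and none on day 13 in 23.7 M reads, which allows up to 0.127 CPM; 5 transcripts showed the opposite.

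The 970 transcripts that rose had a median log2 level of 1.70 on day 7, 1.74 on day 10, 0.69 on day 13, 3.94 on day 16 and 3.22 on day 19. The 429 that fell had 4.12, 4.27, 5.29, 3.09 and 3.13 on the same days. Both sets were chosen by their day 13 and day 16 values, which by itself sets their day 13 median apart from the other days. ENSBTAT00000018521 was at 2145 ± 1424 RPKM on day 7 (n = 5) and 4367 ± 2942 on day 10 (n = 7). A set of 65 transcripts, chosen after the values were seen as those above 50 CPM on both late days and at least 50 times their level in day 13 replicates 1 to 4, took 8.60 ± 2.11% of the other reads on day 16 and 7.87 ± 1.44% on day 19. It took 2.43 ± 1.13% on day 10 and 1.54 ± 0.96% on day 7, but at most 0.0231% in day 13 replicates 1 to 4, where the choice of the set requires low values, and 2.78% in day 13 replicate 5.

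**Figure D3:**
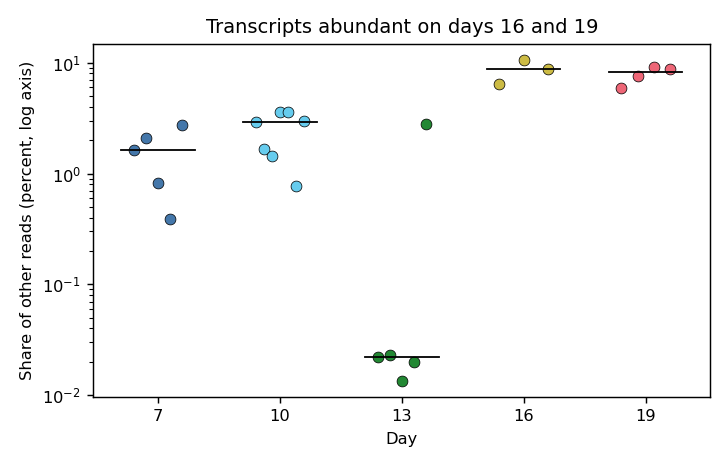
Points give, for each of 24 replicates, the percent of reads (without the most abundant transcript, log axis) in the 65 transcripts abundant on days 16 and 19, by day, with a line at the median. On day 13, 4 replicates lie at or below 0.0231% and replicate 5 at 2.78%, inside the range of days 7 and 10.

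The RNA of days 13 and 16 was also prepared differently, so stage and preparation cannot be told apart in this comparison. The count was 449 without day 16 replicate 4, 638 without replicate 1, 746 without replicates 2 and 3 (1 sample) and 930 without day 13 replicate 3. Quantile normalization gave 1026 higher and 705 lower, a lower share of rises than the 970 and 429 above; the model of these 2 days alone gave 1046 and 917, and all 28 libraries as labelled 537 and 502. With day 16 replicates 2 and 3 as separate samples, 2153 were called, 1375 higher and 778 lower. Without the filter, which leaves out transcripts that reach 1 RPKM on day 16 alone, 1274 were higher and 429 lower. Without day 13 replicate 5 and the pair of libraries rich in the 92-nucleotide transcript, 1262 were higher and 934 lower.

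**Figure D4:**
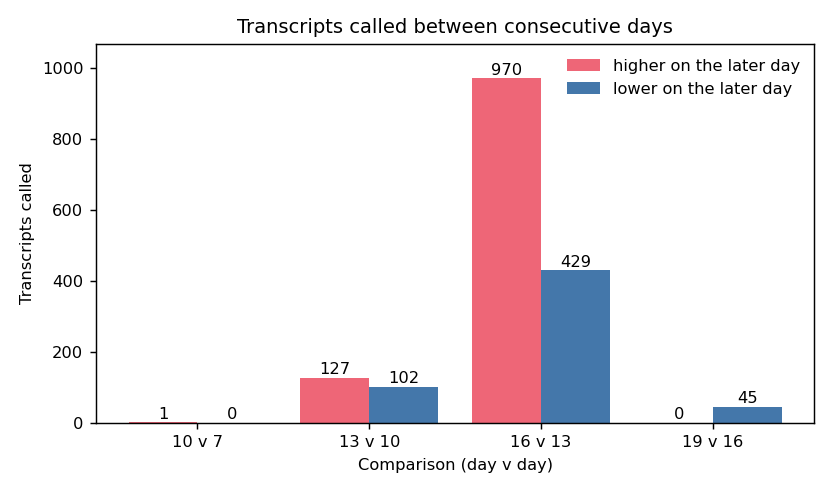
Bars give the number of transcripts called higher (red) or lower (blue) on the later day in each comparison of consecutive days, with the number above each bar. The step from day 13 to day 16 holds 970 and 429, and the other steps 229 or fewer in all.

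The last comparison asked what changes between recognition and attachment. From day 16 to day 19, 45 transcripts fell and 0 rose (0.235% of those tested); limma p was under 0.05 before adjustment for 1295, and voom called 2 higher and 1061 lower. ENSBTAT00000054985 (119 nucleotides) fell from 366 ± 194 RPKM (SD, n = 3) to 2.59 ± 1.67 (n = 4; log2 change -6.67 ± 1.46 SE, adjusted p = 0.049). ENSBTAT00000051166 (109 nucleotides) fell from 43.0 ± 26.7 RPKM to no read, at least 57.9-fold below the day 16 level when 3 reads over the whole of day 19 set the floor (adjusted p = 0.0014; no read in 4 of 4 day 19 replicates). The 45 were short, with a median of 703 nucleotides against 1677 for all tested, and weakly read, with a median of 42 reads over the whole of day 16. Transcripts that reach 1 RPKM on day 16 alone could not be among them, since the filter asks for 4 replicates and day 16 has 3. Without the filter 302 fell and 0 rose. ENSBTAT00000051166 passed the filter only through day 7 replicate 1, at 38.2 RPKM. In the same direction, 106 transcripts had a read in every day 16 replicate and none on day 19 in 37.0 M reads (up to 0.081 CPM), and 1 the opposite.

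The call of ENSBTAT00000054985 ended in 18 of its 24 alternatives, 2 of them the pseudocounts of 0.1 and 0.5, while its log2 change was -3.30 with all 28 libraries as labelled, -5.13 with total reads as a covariate and -6.27 to -8.38 in the other 16. The call of ENSBTAT00000051166 ended with all 28 libraries as labelled (log2 change -2.75, adjusted p = 1). It did not pass the filter, and so has no value, at equal depth, in the 2-day model or without any 1 day 16 replicate. The median change of all tested transcripts was -0.17 between these days and 0.17 after median centring, under which 20 fell and 0 rose. The number of falls was 0 without day 16 replicate 4, 11 without day 16 replicates 2 and 3 (1 sample), 13 without day 16 replicate 1, 24 without day 19 replicate 4, 26 without replicate 3 and 28 without replicate 2, and 0 with all 28 libraries as labelled. The model of these 2 days alone called 27, with 1 of the 45 among them, and at equal depth 22 were called, with 8 of the 45 among them. The filter acts anew in both, and where a day 16 replicate is left out. Members of the 45 near 0 on day 19 can fail it there, so a lost call is not always a failed test. How many failed it is not given here. With day 16 replicates 2 and 3 as separate samples, 78 fell, with 41 of the 45 among them. It was also 30 without day 19 replicate 1, within 1.5 times the 45.

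**Figure D5:**
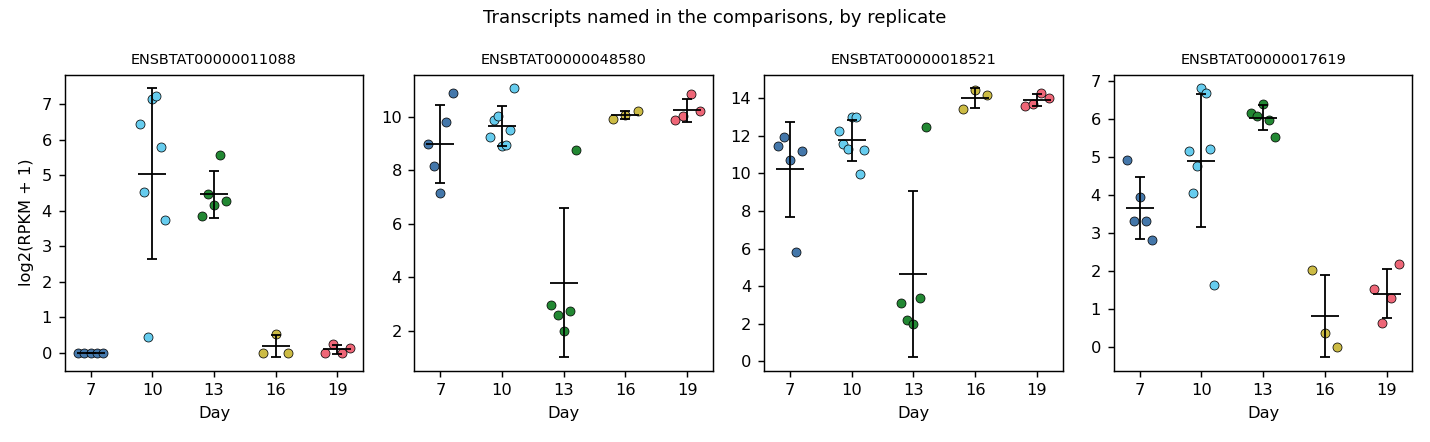
Points give log2(RPKM + 1) of 4 named transcripts in each replicate by day, with bars for the mean and SD. ENSBTAT00000011088 appears on day 10, and ENSBTAT00000048580 and ENSBTAT00000018521 are low on day 13 except in replicate 5.

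Over all 5 days, 2131 of 19186 transcripts varied (11.1%; limma moderated F test), 224 of them by at least 4 on the log2 scale. The highest mean fell on day 16 for 725 transcripts, on day 13 for 557, on day 7 for 479, on day 19 for 320 and on day 10 for 50. The lowest mean fell on day 13 for 667, on day 19 for 576, on day 7 for 568, on day 16 for 214 and on day 10 for 106. The commonest combination, in 410 transcripts, was lowest on day 13 and highest on day 16.

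Part of the changes into day 13 had the opposite sign by day 16. Of the 127 transcripts higher on day 13 than on day 10, 67 were lower again on day 16, where independent lists would share 2.84; of the 102 lower on day 13, 90 were higher again on day 16, where independent lists would share 5.16. Both comparisons use the same day 13 replicates, which alone favours opposite signs, so these overlaps overstate the return. With separate day 13 replicates for each comparison, over 20 divisions of the 5, the overlaps were 1 to 11 (median 4) and 0 to 34 (median 22), and those in a shared direction at most 1. All 45 transcripts lower on day 19 than on day 16 were among the 970 higher on day 16 than on day 13 (independent lists 2.28); day 16 has too few replicates to divide, and part of that overlap can come from its shared replicates.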

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

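All tests of explanations in this part were chosen after the results were seen, including the limits that decide them and the counts over other splits of the replicates. For the mixed sample, a first limit from simulated dilution was replaced, once its result had been seen, by the spread among the late replicates.

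In each day with 4 to 7 replicates, 4 library measures and the 12 named transcripts were searched for a replicate far from the others. Of 60 such groups, 14 had one, where chance gives about 1 in 20, or 3, if groups are independent and values normal. These groups are not independent. ENSBTAT00000042502 enters both as a share and as a level, and ENSBTAT00000053388 and ENSBTAT00000018521 stood apart in the same libraries. The excess over 3 is therefore not measured. The share of reads in the most abundant transcript stood apart in day 7 replicate 5 (34.3%, the others 0.287 to 2.99%), day 10 replicate 7 (38.4%, the others 0.277 to 5.11%) and day 19 replicate 1 (3.22%, the others 0.108 to 0.160%); in the last, ENSBTAT00000042502 was at 18.42 on the log2 scale. Day 19 replicate 1 was also the shallowest of its day, at 5.34 M reads (1e6), and held ENSBTAT00000057026 at 5.99 on the log2 scale against 1.60 to 2.20. In day 10 replicate 7 the next 10 transcripts took 8.43% of the other reads (the others 4.88 to 6.37%). Day 13 replicate 5 had 12460 transcripts with a read at equal depth (the others 13557 to 13690) and the log2 levels 8.76 for ENSBTAT00000048580, 12.02 for ENSBTAT00000053388 and 12.46 for ENSBTAT00000018521. In day 7 replicate 4 the last of these stood at 5.80 and ENSBTAT00000053388 at 5.30. ENSBTAT00000051166 was at 5.29 in day 7 replicate 1, on only 3 reads, and had no read in the other 4 of that day.

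The 3 libraries whose label and file title differ on the day were set against the means of both days, over the transcripts called between those days. Day 16 replicate 5 was nearer day 19 at 100% of 45 transcripts (day 16 replicates 0 to 13.3%), day 19 replicate 5 was nearer day 7 at 87.6% of 1303 (day 19 replicates 0.077 to 3.38%), and day 7 replicate 6 was nearer day 16 at 77.9% of 831 (day 7 replicates 1.80 to 23.0%). Replicates of the day in the title stood at 100%, 63.5 to 98.2% and 91.0 to 99.6% in the same order. Day 7 replicate 6 thus lay below every day 16 replicate, though those took part in the calls and it did not. All 45 transcripts fell from day 16 to day 19, so a library that lacks them is nearer day 19 whatever its day. Day 13 replicates held them at only 5.69 to 10.5 CPM. The 100% of day 16 replicate 5 therefore sets it apart from the day 16 replicates but does not place it on day 19. Low depth is argued against, since at equal depth the lowest of the 3 shares was still 72.9%, above the 20.3% reached by any day 7 replicate. A candidate explanation is that these 3 files belong to the day of the sample whose title they carry, with 77.9% as the lowest share. For day 7 replicate 6 the day mark in the file name goes against it, since that mark matches the label. For day 16 replicate 5 the share leaves the day open. No biological explanation was tested, and the 9 other libraries with a displaced title keep their day under either reading.

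The 65 transcripts abundant on days 16 and 19 also took reads on days 7 and 10 and in day 13 replicate 5, but hardly in the other 4 day 13 replicates, on whose low values the set was chosen; in day 7 replicates 4 and 5 and day 10 replicate 7 the median member was far below its late level (log2 ratio -6.68, -4.34 and -4.36, against -7.18 to -7.89 in those 4), so few members carried the share there. Each of the 13 libraries held at least 16.8 times the reads that the highest rate of those 4 gives at its own depth. The choice of the set kept that rate low, so this multiple does not test depth. Thinning moved the lowest of the 13 shares little: in day 7 replicate 4 it was 0.388%, and 0.395% at equal depth. In 8 of the 13 the set kept nearly 1 ratio to the late libraries, with interquartile ranges of the log2 ratio of 0.65 to 1.15, no wider than among the late replicates themselves (0.35 to 1.26), so material or reads of late conceptuses in these libraries are a candidate explanation. In the other 5 the range was at least 1.76, and counting noise at low levels was not separated, so a mixture cannot be told apart there. Expression of the set in early embryos, lost by day 13 and regained by day 16, stays open and untested.

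The 45 transcripts lower on day 19 than on day 16 had 2779 reads on day 16 and 81 on day 19, where the greater depth of day 19 would give 8707. They were called on RPKM, which is already scaled to depth, so this gap restates their choice and does not test depth. At equal depth 8 kept their call, with a median of 4 reads left on day 16, yet 44 still fell by at least 1 on the log2 scale (median -2.40 against -2.76). A further count took 2219 transcripts with a read on day 7 or 10 and none on days 13 and 19. Of these, 43.9 to 54.0% had a read in a day 16 replicate, where 1 even rate per base gives 84.4% or more. That argues against a strictly even rate only. An uneven background, from genomic DNA or otherwise, was not tested and stays open. A difference between libraries that is not tied to day 16 cannot be told apart: the set stood 15.4 times above the median of the others in day 7 replicate 1 and 5.83 times in day 10 replicate 1, with reads of 15 of the 45 in each, but 9.999 and 3.397 times without ENSBTAT00000054985. A member under 1 RPKM in all day 19 replicates was tested only if a replicate of days 7, 10 or 13 reached that level. A single read does so more readily in a shallow library. Part of these multiples can therefore come from the choice of the set. Of the 3 libraries left out, day 19 replicate 5, of day 16 by neither label nor file title, held reads of 40 at 534 CPM. That is above every day 16 replicate (159 to 507 CPM), so high levels of the set were not confined to day 16. Day 7 replicate 6, titled for day 16, held 30 at 172 CPM. Day 16 replicate 5, titled for day 19, held 5 at 0.685 CPM. Whether stage or another property of the libraries sets these levels stays open, as does a biological change.

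Other splits of the same replicates were counted for each comparison. For day 10 against day 7, 39 of 100 splits called at least the 1 transcript of the real one, so chance cannot be excluded; another split called 853, which points to a structure among these libraries other than day. For day 13 against day 10, only the real split of 100 called as many as 229 (highest other 176). For day 16 against day 13, 1 of 56 splits, the real one, called 1399 (highest other 86), and for day 19 against day 16, 1 of 35 called 45 (highest other 1). For the 5 days together, 1 of 100 regroupings called 2131 (highest other 54). In each of these 4, taken singly, chance is excluded at 1 in 20, and 1 of 56 and 1 of 35 are the smallest shares these numbers of replicates allow. A difference between libraries that goes with the day is not excluded, and the 45 became 0 without day 16 replicate 4.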

How the results depend on the processing

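Pseudocount, filter, scaling, samples in the model, variance model, sample weights and, for the numbers called, each replicate in turn were fixed in advance. Voom, equal depth, other totals, the depth covariate, separate day 16 replicates 2 and 3, the omission of libraries that stood apart and, for the correlations, each replicate in turn were chosen after seeing the data. The cause of each difference was not tested.

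For day 10 against day 7 (1 called), median centring gave 3, quantile normalization 3, a model of only these 2 days 0, sample weights 1354, voom 111, equal depth 2, totals without the most abundant transcript 4, the covariate 5, omission of both libraries rich in that transcript 108, and of day 13 replicate 5 as well 180. For day 13 against day 10 (229), a model of the 2 days gave 35, sample weights 1664, voom 619, equal depth 109, the covariate 83 and omission of the 3 libraries 453. For day 16 against day 13 (1399), sample weights gave 5251, voom 3493, separate replicates 2 and 3 2153 and omission of the 3 libraries 2196. For day 19 against day 16 (45), no filter gave 302, a filter at 5 RPKM 7, median centring 20, the 2 days alone 27, all 28 libraries as labelled 0, sample weights 1718, separate replicates 78, voom 1063, equal depth 22, the covariate 27 and omission of the 3 libraries 39. For the 5 days together (2131), all 28 libraries gave 1015, sample weights 10060, voom 5857 and omission of the 3 libraries 3565. The estimate of sample weights stopped before it converged.

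Leaving out a replicate at a time gave 1 to 92 for day 10 against day 7, 90 to 350 for day 13 against day 10, 449 to 1685 for day 16 against day 13, 0 to 30 for day 19 against day 16 and 1479 to 2640 over the 5 days. The difference between correlations within and between days, 0.026, ran from 0.019 to 0.038. Of 288 values of the named transcripts under alternatives, 258 kept direction and call, 30 lost the call and 0 turned; 18 of the 30 were ENSBTAT00000054985. Voom took ENSBTAT00000011088 to an adjusted p of 0.0635 and the 2-day model to 0.361. Of the 45 falls on day 19, 41 were kept with separate day 16 replicates, 8 at equal depth and 1 in the 2-day model. In the last 2 settings, members near 0 on day 19 could fail the filter and go untested.

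Gene list tests and the named gene panel were not run for want of names, nor were the count tests planned for recovered reads, since the deposited unit is RPKM. No paired analysis was possible because no label ties replicates of different days to each other. The shallowest single library, of day 7, has 473552 reads, which allow up to 6.34 CPM for a transcript without a read.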

Other observations

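The tests of this part were not planned. From day 7 the number of transcripts called grew with time: 1 for day 10, 775 for day 13, 831 for day 16 and 1303 for day 19 (limma, all pairs of days in 1 model). From the late days it did not. Day 13 differed from day 19 in 1220 transcripts and from day 16 in 1399, whereas day 10 differed from day 19 in 176 and from day 16 in 212. The correlations do not show day 13 as the farther day: its mean with day 19 was 0.836 against 0.796 for day 10, and with day 16 0.756 against 0.752. The count of calls also depends on the spread and number of replicates, and day 10 was the least uniform day, at 0.739.

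ENSBTAT00000011088 was read only on days 10 and 13 beyond a trace: 1758 reads on day 10, 601 on day 13, 4 on day 16, 3 on day 19 and 0 on day 7.

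Day 10 replicate 7 and day 7 replicate 5, the pair richest in ENSBTAT00000042502, had similar reads despite their labels. Without that transcript their reads differed by a mean chi-square of 1.91 per transcript, where sampling noise gives 1, and 13.5% of 9234 transcripts passed the 5% point. This measure grows with depth, and both libraries are shallow, so it does not rank pairs of unlike depth. At equal depth their Pearson correlation was 0.917 across transcripts, below the 0.942 of day 16 replicate 5 with day 19 replicate 3. It was still the highest that either had with any library. Within their own days the highest were 0.888 for day 10 replicate 7 and 0.899 for day 7 replicate 5. The comparison of day 10 with day 7 kept them as separate replicates on opposite sides. Whether they share material cannot be told from these values. By the same chi-square, 2 libraries with a displaced title were near one of the day in that title: day 7 replicate 6 with day 16 replicate 1 (3.54, correlation 0.912) and day 19 replicate 5 with day 7 replicate 1 (4.48, correlation 0.883).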
